A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

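RNA of budding yeast from 3 chemostats was measured on 22 two-colour arrays. Per the labels, the sample was labelled with Cy5 and a pool of RNA from glucose and galactose cultures with Cy3. The chemostats are called no3AT, 3AT40mM and no3AT2, the second with 40 mM 3AT (3-amino-1,2,4-triazole, a competitive inhibitor of the histidine enzyme His3). Each was sampled at steady state in galactose, then in glucose before a steady state, then at steady state in glucose. Per the labels, the arrays of no3AT2 carry polyA RNA and those of the other chemostats total RNA. The labels name hot phenol extraction and refer to a web site for the labelling. Scanning, background correction, normalization, spot filters and the log base are not given in the sources used here.

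The deposited table holds 1 column per array with 6281 rows and no intensities. Its values were taken as log2 ratios of sample over reference, as deposited: they are signed and lie around 0, which shows a log scale, but the base is not stated. If the base were another, the log2 values given here would scale with it. The 2-fold counts and the alternative with a 2-fold minimum would change, though not in proportion, while the other tests would not change. Of the 6281 row IDs, 5763 matched a gene in a table of the R64 assembly, 57 of them by an older or second name, and 518 did not. The arrays' own build is not named, so no coordinates are given. The 76 rows that shared a gene with another row were averaged with it, leaving 6242 genes. Array medians lay between -0.15 and 0.07 as deposited, so each array was centred on its median, by the rule that centring applies if any median is over 0.1 from 0. Genes with a value on at least 80% of the arrays and in each of the 9 combinations of chemostat and phase were tested (4783 genes). The number of arrays limits the precision, and depth is unknown because no intensities are given.

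Early glucose stands for the 2 lowest labelled hours in glucose of each chemostat. The 5 later glucose arrays before steady state entered no fit and are described array by array. These definitions, the comparisons, tests, gene lists, rules for naming genes and most alternatives were chosen before the data were examined. Changes shared by the chemostats were tested with limma 3.58.1 in R 4.3.3 on the 9 means per chemostat and phase of 17 arrays, with the chemostat as a block, so that the chemostat is the replicate (4 residual and 10.4 prior degrees of freedom). Changes within a chemostat and differences between chemostats came from a limma fit of the same 17 arrays with 1 mean per chemostat and phase (8 residual and 11.4 prior degrees of freedom). Its p-values measure the spread between arrays of one culture, which may be technical, and say nothing of other cultures. A phase with a single array is assumed to vary like the others. P-values are two-sided and adjusted by Benjamini-Hochberg over the 4783 genes of each comparison, with a threshold of 0.05.

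In all, 32 gene lists with at least 3 measured members were tested with limma's camera with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of each comparison. Per chemostat and between chemostats they were tested on the 3270 genes with a value on all 17 arrays, a step added after the data were seen. Genes named are the 10 largest increases and decreases past the threshold with the same sign in all 3 chemostats, GAL1, GAL2, GAL7, GAL10 and HIS1 to HIS7, up to 4 members with the largest change of each list described, and up to 5 of the largest differences each way between chemostats. GAL2, GAL10 and HIS2 had too few values to be tested. The per-array count is of genes over 2-fold from the mean of the chemostat's own galactose arrays. Correlations of changes are across genes, which are not independent replicates.

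The alternatives were the values as deposited, quantile normalization, other filters on missing values, another choice among rows of one gene, a 2-fold minimum, robust and trended moderation, arrays as units, no block, other definitions of early glucose, other sets of arrays, and leaving out each chemostat and each array. Added after the data were seen were the median of the chromosome arm removed from each value, and the median of the 10 rows on either side at steps of 2 in the deposited order removed from each value, called neighbour-corrected below. The last was also run without the 3AT40mM array at 552 hours and with arrays as units, and the lists were tested on it.

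The fits were tested on simulated data with 200 of 4783 genes changed by log2 sizes of 1, 2 or 3 and independent noise of the size seen in each gene. This noise does not depend on row order, as the deposited values do, so the shares and false calls below need not hold for the real counts. For glucose against galactose steady state over 3 chemostats, the test recovered 44.8% of changes of size 1 and 100% of those of size 2 and of size 3, with 9 false calls among 172. For the early change of no3AT2 minus no3AT it recovered 0% at size 1, 22.4% at size 2 and 77.3% at size 3, with 5 false calls among 71. For the early change of 3AT40mM minus the cultures without 3AT the shares were 2.99%, 49.3% and 95.5%, with 2 false calls among 100. A respiratory chain list raised by 1 in simulated values had an adjusted p of 0.068 with an estimated correlation, so that this setting missed it, against 1.41e-14 with the preset one. The simulated genes were independent, so this cannot show which setting is right for the arrays, where neighbouring rows correlate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.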

Results

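Steady galactose cultures of budding yeast were switched to glucose in 3 chemostats, and RNA levels were measured against a common reference pool on 22 arrays. The no3AT chemostat has 2 galactose arrays, 4 glucose arrays before steady state and 2 at glucose steady state. The 3AT40mM chemostat, which held 40 mM of the His3 inhibitor, has 2, 5 and 1. The no3AT2 chemostat, a second culture without inhibitor, has 1, 2 and 3. An array lacked between 138 and 1587 of the 6281 values (median 548). Across genes, arrays of the same chemostat and phase, with early and later glucose kept apart, correlated at -0.20 to 0.76 (median 0.53, 13 pairs). Glucose arrays correlated with each other at -0.25 to 0.80 (136 pairs), and galactose with glucose arrays at -0.44 to 0.87 (median -0.04, 85 pairs).

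Early glucose was compared with galactose steady state to ask which genes responded to the switch in all cultures. The galactose gene GAL7 and HIS3, a gene of histidine synthesis, were among those that fell furthest. From what is known of the study, though not from its labels, HIS3 is under the GAL1 promoter, so its values need not show how a native histidine gene responds. GAL7, the uridylyltransferase of galactose breakdown, fell by 2.54 on the log2 scale (SE 0.34, adjusted p = 0.0093, n = 3 chemostats, lower in all 3). It had no value at 353 hours in no3AT and at 328 hours in no3AT2. HIS3 fell by 2.35 (SE 0.50, adjusted p = 0.0150, lower in all 3). GAL1, the galactokinase, fell by 1.70 (SE 0.40, adjusted p = 0.0228), and HIS6, another histidine enzyme, by 1.32 (SE 0.28, adjusted p = 0.0157), each lower in all 3. HIS1, HIS4, HIS5 and HIS7 did not pass, at 0.78, 0.48, -0.23 and 0.00, the last at -0.02 with quantile normalization. HIS5 turned to 0.31 with no3AT2 left out, and with the neighbour-corrected values the 4 stood at 0.33, 1.06, 1.06 and 0.75, also without passing. In all, 340 of 4783 genes changed, 12 up and 328 down, and 1116 had an unadjusted p under 0.05.

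Of 8 measured genes of the GAL pathway, 4 fell, and 4 when adjusted over the list alone. Besides GAL7 and GAL1 these were GAL3, the galactose sensor, at -1.42 and FUR4, a uracil permease encoded beside the GAL genes, at -1.67. The list was lower as a group (median -1.05, camera adjusted p = 0.0053), but adjusted p = 0.85 with an estimated correlation. Genes for sucrose and maltose use were lower too (median -0.75, adjusted p = 0.0031, and adjusted p = 0.85 with an estimated correlation). There 4 of 11 fell, with SUC2, the invertase, at -1.68, MAL13 at -1.49 and MAL31 at -1.18. When adjusted over the list alone, 9 fell and 1 rose. Glycolysis and fermentation genes were higher (median 0.67, adjusted p = 0.0027, and adjusted p = 0.91 with an estimated correlation). Of its 21 genes, PDC5, a pyruvate decarboxylase, rose by 1.33 (SE 0.32) and TPI1, triose phosphate isomerase, by 1.33 (SE 0.36), and these 2 were also the count adjusted over the list alone. ENO2, an enolase, stood at 1.32 and PDC6 at 1.33 without passing. The list was not higher in every culture: its median was -1.03 and -0.11 on the early arrays of no3AT2, and 0.0050 at 552 hours in 3AT40mM.

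Other lists had smaller medians over the 3 chemostats. Amino acid biosynthesis genes under Gcn4, the activator of the amino acid starvation response, had a median of 0.28 (camera adjusted p = 0.0314), cytosolic ribosomal protein genes 0.19 (adjusted p = 0.0128) and proteasome genes 0.38 (adjusted p = 0.0128). Respiratory chain and ATP synthase genes had a median of -0.41 (adjusted p = 0.0128). Each of these 4 had adjusted p = 0.91 with an estimated correlation. In early no3AT2 the first 2 lists went the other way, with medians per array of -0.92 and -0.37 for Gcn4 and of -1.06 and -0.63 for ribosomal proteins, against 0.59 and 0.87, and 0.56 and 0.84, in no3AT. With the neighbour-corrected values 5 of the 7 lists passed, and the ribosomal protein (adjusted p = 0.0824) and proteasome (adjusted p = 0.0976) lists did not. The 5 each had adjusted p = 0.77 with an estimated correlation. COX5B, a cytochrome oxidase subunit, fell by 1.10 as the 1 of 32 respiratory genes that passed, and as the 1 adjusted over the list alone. In the other 3 lists 0 of 37, 0 of 124 and 0 of 31 genes passed limma's test, and 0 when adjusted over the list alone. LYS9 of lysine synthesis stood at 1.48, SNO1 at 0.93, RPL18B at 0.89 and the proteasome subunit PRE8 at 0.97.

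The genes with the largest increases beyond those named were ZPS1, a cell wall protein of zinc shortage, at 1.54 and ERR3, an enolase-like protein, at 1.47. PEX5, the peroxisomal import receptor, rose by 1.14, RAD52 of DNA repair by 1.09, CTF13 of the kinetochore by 1.03, COG7 of Golgi transport by 1.00, NAS6 of proteasome assembly by 0.99 and the pyrophosphatase IPP1 by 0.92. Among the decreases, MRPL8 of the mitochondrial ribosome stood at -2.41, INO1, inositol phosphate synthase, at -2.14, THP2 of mRNA export at -2.05 and SGA1, a glucoamylase, at -1.97. CNM1 stood at -1.93, MOB1 of mitotic exit at -1.88, the chaperone JEM1 at -1.88 and FUN14 at -1.87. Of the rows next to a fallen gene in the deposited order, 81.9% were below 0, against 48.2% of all rows. With the neighbour-corrected values 0 genes passed limma's test (790 at an unadjusted p under 0.05). Of the 340 genes, called on the same arrays before this correction, 330 kept their sign. The median of the 328 fallen genes went from -1.30 to -0.62 with these values. GAL7 at -2.68 (SE 0.41, adjusted p = 0.1051), HIS3 at -2.28 (SE 0.51, adjusted p = 0.1510) and GAL1 at -1.74 (SE 0.49, adjusted p = 0.1768) stayed about as large there, and HIS6 stood at -0.86 (SE 0.24, adjusted p = 0.1768). The count was also 0 without the 3AT40mM array at 574 hours or the lone galactose array of no3AT2, and without the no3AT arrays at 305, 316, 344 and 507 hours it was 522, 148, 160 and 186.

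Glucose steady state was compared with galactose steady state to ask what remained different after adaptation. HIS3, with the promoter noted above, had the largest decrease among named genes, at -2.90 (SE 0.50, adjusted p = 0.0033, n = 3 chemostats, lower in all 3), and also fell with the neighbour-corrected values, at -3.30 (adjusted p = 0.0371). HIS6 fell by 1.69 (SE 0.28, adjusted p = 0.0030) and GAL7 by 1.57 (SE 0.34, adjusted p = 0.0084), while GAL1 at -1.18 missed the threshold (adjusted p = 0.0584). HIS1, HIS4, HIS5 and HIS7 did not pass, at -0.33, -0.25, -0.67 and -0.41, or with the neighbour-corrected values, where 3 turned sign, at -0.32, 0.43, 0.89 and 0.46. PEX5 rose by 1.81 (SE 0.26, adjusted p = 0.0029, higher in all 3), and by 1.92 with the neighbour-corrected values (adjusted p = 0.0305). In all, 840 of 4783 genes changed, 217 up and 623 down, and 1654 had an unadjusted p under 0.05.

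Glycolysis was the list called at glucose steady state (median 0.93, camera adjusted p = 0.0098), with adjusted p = 0.86 with an estimated correlation. The GAL pathway (median -0.87) and respiratory chain (-0.30) lists also passed with the neighbour-corrected values (adjusted p = 0.0133 for both, and adjusted p = 0.81 with an estimated correlation). Of the 21 glycolysis genes 4 rose, and 6 when adjusted over the list alone. GPM1, phosphoglycerate mutase, rose by 2.01 (SE 0.47), TPI1 by 1.62 (SE 0.36) and ENO2 by 1.59 (SE 0.52), while ENO1 at 1.32 did not pass. Among other increases, LYS9 rose by 2.08, the peroxidase AHP1 by 1.87, the sugar transporter gene MPH3 by 1.63 and ZPS1 by 1.61. HAP1, a haem-dependent activator, rose by 1.54 and RFC2 of DNA replication by 1.52. Among the decreases, INO1 stood at -2.70, MRPL8 at -2.50, THP2 at -2.32, SGA1 at -2.32 and MOB1 at -2.18. APQ12 of the nuclear envelope stood at -2.22, the transporter gene AVT2 at -2.20, ESC8 at -2.14 and MET28, a regulator of sulfur metabolism, at -2.14. Of the 840 genes, 15 also passed with the neighbour-corrected values, among them AVT2 (adjusted p = 0.0371), ESC8 (0.0455) and APQ12 (0.0495), where 20 genes passed in all, 7 up and 13 down. The sign was kept in 794 of the 840, which were called on the same arrays before this correction. The median of the 623 fallen genes went from -1.23 to -0.53. Neighbour-corrected, INO1 stood at -1.59, MRPL8 at -1.60, THP2 at -1.55, SGA1 at -1.50, MOB1 at -0.83 and MET28 at -1.14, without passing.

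Leaving out 1 array moved this count to between 302 and 1115. It was 302 without the lone no3AT2 galactose array, 336, 363 and 502 without 3AT40mM at 937 hours, 3AT40mM at 552 hours and no3AT2 at 328 hours, and 453, 354 and 525 without no3AT at 316, 344 and 507 hours. Among the genes fixed in advance, HIS3 and HIS6 passed in all 29 alternatives chosen in advance that gave them a value, and GAL7 in 22 of 26. With the neighbour-corrected values HIS6 at -1.03 (adjusted p = 0.0783) and GAL7 at -1.44 (adjusted p = 0.1164) did not pass. Over the 4 settings added for position, HIS3 passed in 3, HIS6 in 1 and GAL7 in 0.

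**Figure D1:**
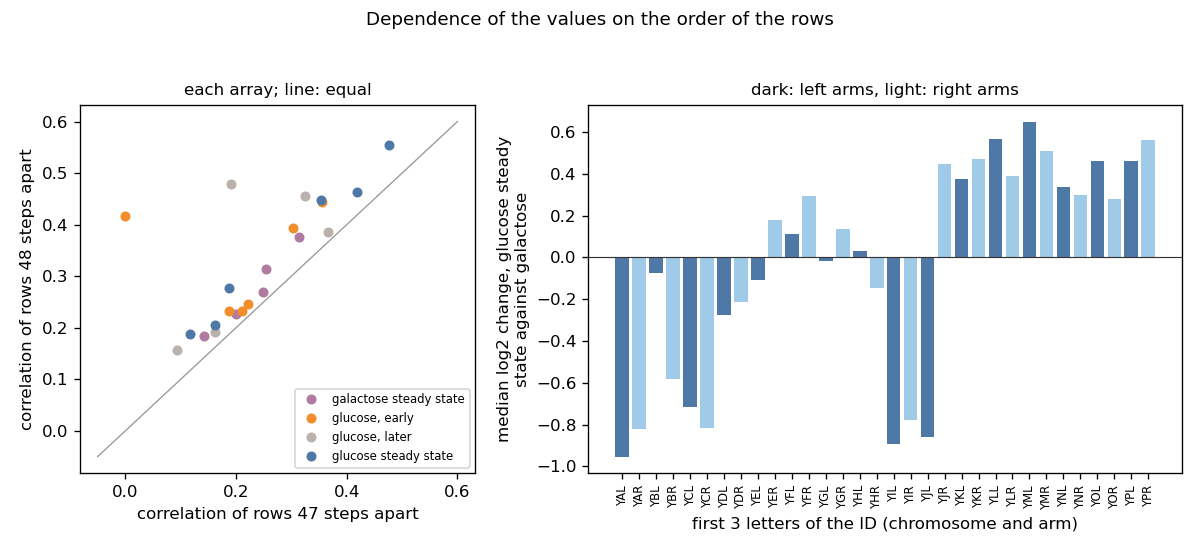
Left, for each of the 22 arrays, the correlation of values 48 rows apart in the deposited order against that of values 47 rows apart, with all 22 points above the line of equality. Right, bars give the median log2 change from galactose to glucose steady state over 3 chemostats for the genes of each chromosome arm, from -0.95 to 0.65.

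Glucose steady state was compared with early glucose to ask which early changes were later lost. No gene passed limma's test over 3 chemostats (0 of 4783, with 344 at an unadjusted p under 0.05), and 0 passed with arrays as units (607 unadjusted). Cytosolic ribosomal protein genes were lower (median -0.36, camera adjusted p = 1.87e-06), 101 of 124 below 0, but adjusted p = 0.94 with an estimated correlation. Histidine biosynthesis genes, HIS3 with its other promoter included, were lower in 6 of 6 (median -0.49, adjusted p = 0.0186), and 16 of 17 heat shock chaperone genes were higher (median 0.51, adjusted p = 0.0023), both with adjusted p = 0.94 with an estimated correlation. These are means over chemostats, and no3AT2 went the other way for the first 2 lists. There the ribosomal protein median went from -1.06 and -0.63 early to 0.11, 0.21 and -0.04 at steady state, and the histidine median from -1.28 and -0.81 to -0.25, 0.04 and -0.48. The Gcn4 list also passed with the neighbour-corrected values (median -0.22, adjusted p = 0.0417, and adjusted p = 0.88 with an estimated correlation). In the first 3 lists 0 genes passed limma's test, also when adjusted over the list alone. RPL4B stood at -1.23, HIS1 at -1.12, HIS4 at -0.73, HIS3 at -0.55, HIS5 at -0.43, HIS7 at -0.42, HIS6 at -0.37, GAL1 at 0.52, GAL7 at 0.97, the chaperone CPR6 at 0.83 and HSP104 at 0.69. With no3AT2 left out, 305 genes passed, 107 up and 198 down. The list results also depend on the 3AT40mM array at 552 hours, which counts as early glucose. Without it, the heat shock list (median 0.32) did not pass camera, while the Gcn4 list (-0.61) did. The ribosomal protein (-0.57) and histidine (-0.55) lists still passed. With an estimated correlation 0 lists passed there. A single array then stands for early glucose in 3AT40mM.

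The other 23 of the 32 lists passed camera in none of the 3 comparisons with the centred values of the 17 arrays. With the neighbour-corrected values, 3 of them passed: oxidative stress at glucose steady state (median 0.50, adjusted p = 0.0159), and between glucose phases ribosome biogenesis (-0.19, adjusted p = 8.83e-04) and sulfur metabolism (-0.27, adjusted p = 0.0151). With an estimated correlation the first had adjusted p = 0.81 and the others adjusted p = 0.88. With the centred values but without the 3AT40mM array at 552 hours, some of the 23 lists passed between glucose phases. These were ribosome biogenesis (median -0.31), histones (-0.39) and sulfur metabolism (-0.52), none of them with an estimated correlation. The 23 lists held sulfur, purine and ergosterol synthesis, mitochondrial ribosomal proteins, ribosome biogenesis, gluconeogenesis and C2 use, the TCA cycle, hexose transporters, general and oxidative stress, multidrug resistance, the phosphate, nitrogen and iron regulons, amino acid transporters, histones, 2 cell cycle phases, cell wall, both mating types, pheromone response and sporulation. The median changes of lists that did not pass lay between -0.33 and 0.41 in early glucose (25 lists), between -0.93 and 0.47 at glucose steady state (31 lists) and between -0.37 and 0.24 between these (29 lists). Median, mean and test differed in sign in 7, 4 and 5 of them, and in 0 of the called lists. By fry, 0 lists passed in any of the 3, with 3, 5 and 1 at an unadjusted p under 0.05.

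Within single chemostats, HIS3 fell in no3AT2, to a change of -3.97 in early glucose (SE 0.79, adjusted p = 0.0353) and of -4.56 at glucose steady state (SE 0.74, adjusted p = 0.0166). In no3AT its steady-state change was -3.17 (adjusted p = 0.0690) and in 3AT40mM -0.95 (adjusted p = 0.5125). GAL7 stood at -2.63, -1.98 and -2.99 in early glucose in no3AT, 3AT40mM and no3AT2, and GAL1 at -1.86, -1.45 and -1.79, without passing. GAL7 had no value at 353 hours in no3AT and at 328 hours in no3AT2, and GAL1 had none at 353 hours. The 3AT40mM change of GAL7 joins unlike arrays, with centred values of -0.81 at 552 hours and -4.87 at 574 hours, against -0.91 and -0.80 in galactose. HIS1 stood at 1.42 and 1.30 in early glucose in no3AT and 3AT40mM but at -0.37 in no3AT2, and HIS4 at 1.17, 1.05 and -0.78. In early glucose limma called 0 genes in no3AT (541 at an unadjusted p under 0.05), 0 in 3AT40mM (469) and 25 in no3AT2, all down (1152). Early no3AT2 had 195 calls with the neighbour-corrected values, 83 up and 112 down. At glucose steady state it called 4 genes in no3AT, all down (716), 0 in 3AT40mM (767) and 66 in no3AT2, 1 up and 65 down (756).

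These counts share 1 estimate of spread, which includes the unlike early arrays of 3AT40mM. Without its array at 552 hours, early glucose gave 54, 1332 and 510 genes in no3AT, 3AT40mM and no3AT2, and with steady-state arrays alone glucose gave 355, 429 and 446.

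Genes over 2-fold from the chemostat's own galactose mean show the course array by array. In no3AT they numbered 420 at 344 hours, 1689 at 353, 1200 at 385 and 1142 at 478, then 944 and 1006 at steady state. In 3AT40mM they numbered 5 at 552 hours, 2220 at 574, 1587 at 592, 643 at 850 and 461 at 878, then 1527 at steady state. In no3AT2 they numbered 2156 at 315 hours and 975 at 328, then 1323, 739 and 1185 at steady state. Arrays differ in the number of genes with a value, so shares can rank otherwise than counts. At 315 hours in no3AT2 the share was 44.4% of 4859 genes, and at 574 hours in 3AT40mM it was 37.6% of 5910. The no3AT2 counts are against 1 galactose array, and the others against the mean of 2. The galactose arrays differed from each other by 295 genes in no3AT and by 23 in 3AT40mM. With the neighbour-corrected values the counts in no3AT were 335, 759, 600 and 808, then 537 and 691 at steady state. The highest there was thus at 478 hours and not at 353. In 3AT40mM they were 1702 at 574 hours, 776 at 592 and 587 at steady state.

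**Figure D2:**
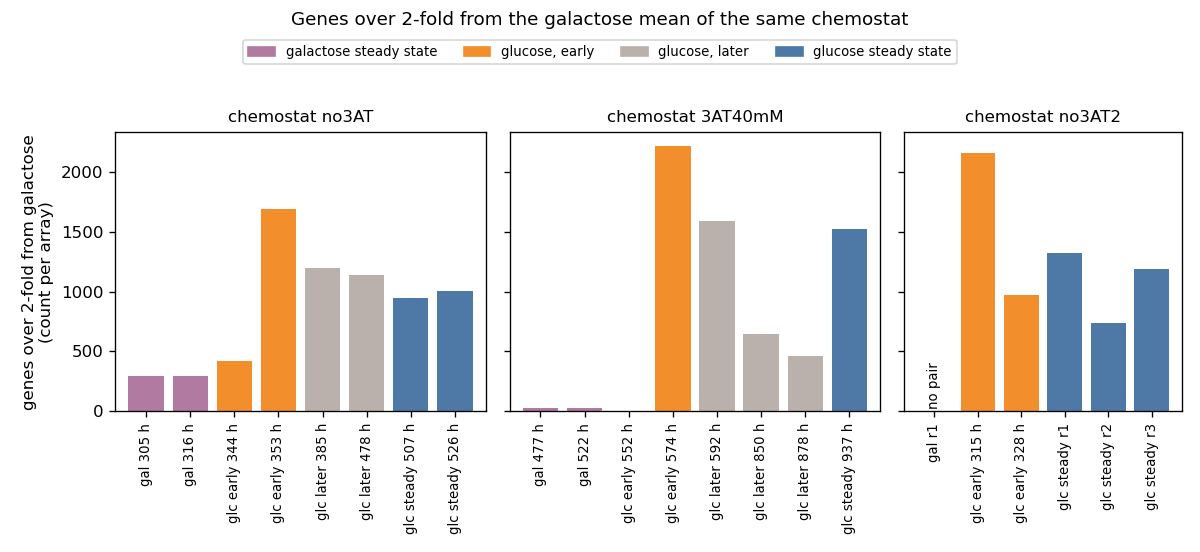
Bars give, for each array, the number of genes over 2-fold from the mean of the galactose arrays of its chemostat, or for a galactose array from the other one. The count is 5 at 552 hours and 2220 at 574 hours in 3AT40mM.

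In 3AT40mM, HIS3, GAL1 and GAL10 were lowest at 574 and 592 hours and nearer to their galactose values later, as single-array values without a test. HIS3 stood at 0.32 and 0.85 in galactose, at 0.65 at 552 hours, at -1.82 and -1.66 at 574 and 592 hours, then at -0.54, -0.28 and -0.37 at 850, 878 and 937 hours, still below both galactose arrays. GAL1 stood at -1.23 and -1.06 in galactose, at -4.26 and -3.17 at 574 and 592 hours and at -0.94 at 937 hours. GAL10, the epimerase, went from -0.58 and -0.02 to -3.92 and -3.80, then to -0.86 at 937 hours. GAL2, the galactose permease, stood at -1.29 and -1.37 in galactose, at -1.65 at 552 and 574 hours, at -2.58 at 592 and at -0.17 at 937 hours. In no3AT, HIS3 stood at -0.12 and 1.02 in galactose, at -1.61 at 344 hours and at -3.53 and -1.91 at glucose steady state. In no3AT2 it stood at 2.62 in galactose and between -2.28 and -1.30 in glucose. The larger steady-state change of HIS3 in the cultures without 3AT (3AT40mM minus their mean, 2.91, SE 0.93) did not pass as a difference (adjusted p = 0.9981).

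**Figure D3:**
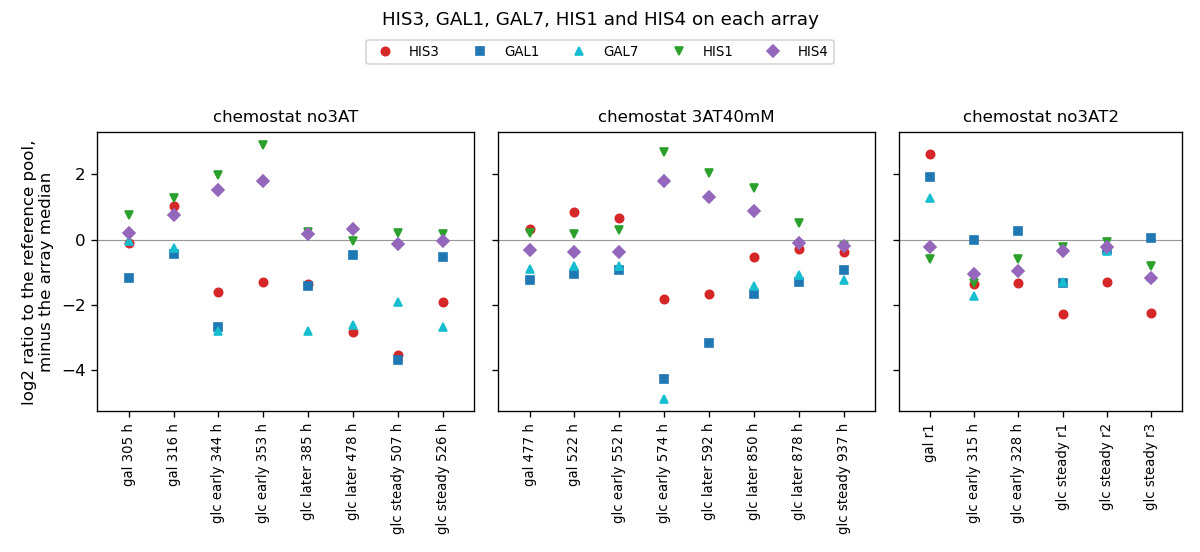
Points give log2 ratios to the reference pool, minus the array median, of HIS3, GAL1, GAL7, HIS1 and HIS4 on each array in the order of the labelled hours. In 3AT40mM, HIS3 stands at -1.82 at 574 hours and at -0.37 at 937 hours.

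Gcn4-dependent amino acid genes and ribosomal protein genes were higher in the early arrays of no3AT and in 3AT40mM from 574 to 878 hours, as medians over each list. The Gcn4 list stood at 0.59 and 0.87 in no3AT at 344 and 353 hours and at -0.10 at 385 hours. In 3AT40mM it stood at -0.09 at 552 hours, at 1.68 at 574, at 1.07 at 592, at 0.60 at 850 and at 0.13 at 937. In no3AT2 it stood at -0.92 and -0.37 early. Ribosomal protein genes stood at 0.56 and 0.84, then at -0.83 in no3AT, at 1.22 at 574 hours in 3AT40mM, and at -1.06 and -0.63 early in no3AT2. HIS1 went to 2.89 in no3AT at 353 hours and to 2.69 in 3AT40mM at 574 hours, and HIS2, measured on fewer arrays, to 2.01 and 1.13. With the neighbour-corrected values HIS1 stood at 1.58 and 2.07 on these arrays, and HIS2 at 1.47 and 0.70.

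**Figure D4:**
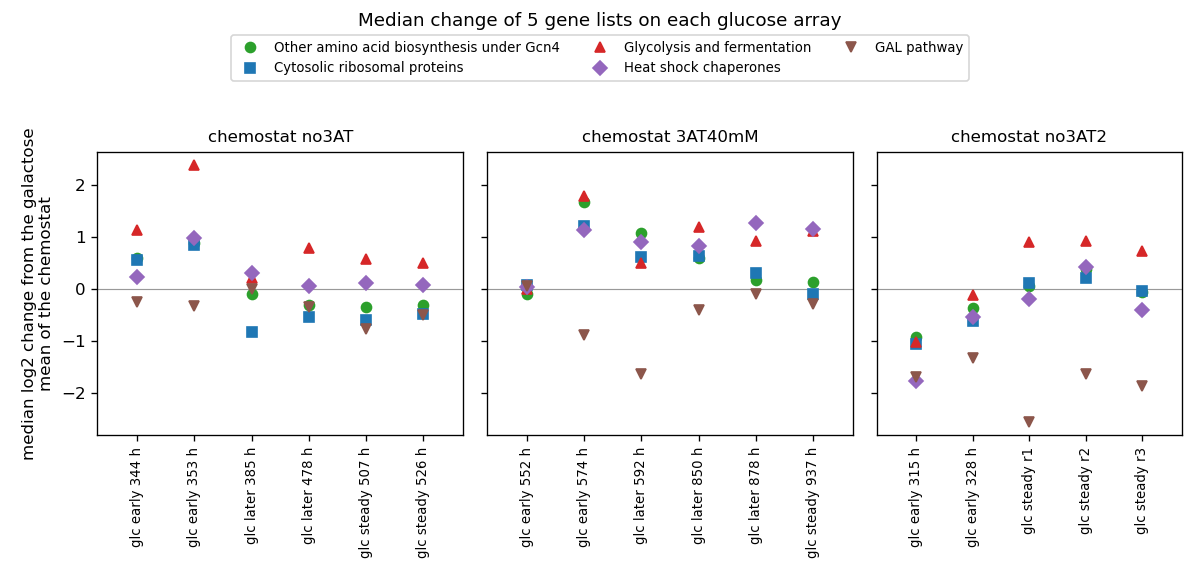
Points give the median log2 change of 5 gene lists on each glucose array from the galactose mean of its chemostat. The Gcn4 list is at 1.68 at 574 hours in 3AT40mM and at -0.92 at 315 hours in no3AT2.

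The cultures without 3AT were compared to ask whether a repeat of the switch gave the same response. They differ in RNA type too, polyA in no3AT2 and total in no3AT, which cannot be told apart from the culture. All changes of no3AT2 rest on 1 galactose array. On it HIS3 stood at 2.62 and GAL1 at 1.91, against at most 1.02 and -0.46 on the other galactose arrays. In early glucose the change was lower in no3AT2 than in no3AT for ATP2, the beta subunit of the mitochondrial ATP synthase, by -3.97 (SE 0.61, adjusted p = 0.0156), and for the RNA helicase gene SKI2, by -3.66 (SE 0.62, adjusted p = 0.0189). The flavohaemoglobin gene YHB1 at -4.00 and the membrane protein gene MRH1 at -3.18 also passed (adjusted p = 0.0393 for both), as did YKR040C at -3.81, which has no name in the table used and is given because the count is small. These 5 genes, 0 up and 5 down, were all that passed (621 at an unadjusted p under 0.05). HIS5 at -2.12, HIS3 at -2.06, HIS4 at -1.95, HIS1 at -1.78, HIS7 at -0.55, HIS6 at -0.47, GAL7 at -0.36 and GAL1 at 0.07 did not pass. Leaving out 1 array gave 0 genes for either no3AT galactose array, no3AT at 353 hours and no3AT2 at 315 hours, 2 for either 3AT40mM galactose array and no3AT2 steady array 1, and 3 for steady arrays 2 and 3. It gave 69 for no3AT at 344 hours, 63 for 3AT40mM at 552 or 574 hours and 41 for no3AT2 at 328 hours.

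As groups, ribosomal protein genes (median -1.65), glycolysis genes (-2.39) and heat shock chaperone genes (-1.77) changed less or in the other direction in early no3AT2 than in early no3AT, with camera adjusted p = 1.12e-22, 4.31e-10 and 0.0012. With an estimated correlation 0 of 31 lists passed, and the smallest was adjusted p = 0.49 with an estimated correlation. At glucose steady state the difference passed for 0 genes by limma (134 at an unadjusted p under 0.05). By camera 7 of 31 lists differed there, 2 up and 5 down, 3 with the neighbour-corrected values, and 0 with an estimated correlation. Across 4783 genes the changes of both cultures correlated at 0.25 in early glucose (Spearman 0.23) and at 0.65 at glucose steady state (Spearman 0.60). With the neighbour-corrected values these were 0.13 and 0.51. With 1 array left out they lay between 0.11 and 0.35 and between 0.48 and 0.68.

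The 3AT40mM culture was compared with the cultures without 3AT to ask whether the inhibitor altered the response, with 1 culture that held it. By camera 7 of 31 lists differed in early glucose from the mean of the cultures without 3AT, 6 up and 1 down, and 0 with an estimated correlation. Against their mean, 0 genes passed in early glucose (315 at an unadjusted p under 0.05) and 0 at glucose steady state (107), by limma. Against no3AT2 alone, a comparison not fixed in advance, as is that with no3AT alone, ATP2 at 3.57 and YKR040C at 3.59 passed in early glucose (adjusted p = 0.0346 for both), and 0 genes passed against no3AT (139 unadjusted). Heat shock chaperone genes were higher at glucose steady state (median difference 1.27), and passed camera with the preset correlation but not with an estimated one. This difference rests on 1 glucose steady-state array of 3AT40mM and in part on 1 galactose array of no3AT2.

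The early result depends on the array at 552 hours. Without it, 131 genes differed from the mean of the cultures without 3AT, 63 up and 68 down. Among the largest increases were ARG1 of arginine synthesis at 3.82 (SE 0.62), ILV5 of branched-chain amino acid synthesis at 3.43 (SE 0.50), URA1 of pyrimidine synthesis at 3.12 and ADE12 of purine synthesis at 3.09. The largest decreases were OMS1 at -2.93, CDC1 at -2.81, LDS1 at -2.60, RVB1 at -2.49 and AGX1 at -2.39. Of 37 genes of the Gcn4 list 8 were higher, and 18 when adjusted over the list alone, with 0 lower. Of these 131 genes, 118 also passed with the neighbour-corrected values. Against no3AT alone 0 genes passed by limma also without that array (795 at an unadjusted p under 0.05), and against no3AT2 alone 344 did.

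Within 3AT40mM without that array, 488 genes rose and 844 fell at 574 hours against galactose. With the neighbour-corrected values 669 rose and 598 fell, and 715 genes passed in both. GAL7 stood at -4.01, GAL1 at -3.11, HIS3 at -2.41 and HIS6 at -2.21, all past the threshold, while HIS1 rose by 2.50 and HIS4 by 2.14. HIS5 at 0.04 and HIS7 at 0.97 did not pass, but did with the neighbour-corrected values, at 1.98 and 2.25 (adjusted p = 0.0016 for both), where HIS6 at -1.20 did not (adjusted p = 0.0826). PDC1, PDC5 and PDC6, pyruvate decarboxylases, rose by 3.55, 3.51 and 3.62. Of the Gcn4 list 23 of 37 genes rose and 0 fell, of glycolysis 14 of 21 rose, and of cytosolic ribosomal proteins 52 of 123 rose, with 24 up and 1 down, 17 up and 65 up when adjusted over the list alone. A single array then stands for early glucose in 3AT40mM, and it is assumed to vary like the others.

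At galactose steady state, 3AT40mM was compared with no3AT to ask whether the inhibitor altered expression before the switch. HIS3 at 0.13, HIS4 at -0.83, HIS1 at -0.82, HIS6 at 0.66, HIS7 at -0.20, HIS5 at 0.15, GAL7 at -0.70 and GAL1 at -0.34 did not pass. No gene passed limma's test (0 of 4783, with 202 at an unadjusted p under 0.05). Cytosolic ribosomal protein genes were lower in 3AT40mM (median -0.73, camera adjusted p = 2.48e-44), with adjusted p = 0.36 with an estimated correlation. Both cultures differ in more than the inhibitor, and there is 1 of each.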

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

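The tests of single arrays in this part, and that of 3AT40mM minus no3AT2, were chosen after the result was seen. Of 86 checks, each of a set of 4 or 5 arrays, 6 found a value that stood apart from the rest of its set. Chance gives about 1 in 20 for replicate arrays. These sets are glucose arrays before steady state at different hours of 1 culture, so that rate need not hold. In 3AT40mM the values that stood apart were GAL7 at 574 hours (-4.87, against -1.41 for the nearest of the 4 arrays with a value) and GAL2 at 592 hours (-2.58). So were the median change of hexose transporter genes at 552 hours (0.0267) and that of genes specific to mating type alpha at 574 hours (-0.82). In no3AT they were HIS6 (-0.83) and HIS7 (0.78) at 344 hours.

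Between cultures, the early change of YHB1 (-4.00), ATP2 (-3.97), YKR040C (-3.81), SKI2 (-3.66) and MRH1 (-3.18) differed in no3AT2 minus no3AT by limma's adjusted p. For 3AT40mM minus no3AT2 the same holds of ATP2 (3.57) and YKR040C (3.59).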

How the results depend on the processing

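Alternatives were chosen before the data were examined, except those for position in the file, which were chosen after the result was seen. The cause of each change was not tested. For single genes, the tallies are per named gene, comparison and setting, and the same call includes genes that passed in neither setting. Among the alternatives chosen before, 1545 gave the same call, 220 were weaker, 12 stronger and 17 reversed in sign. Among those for position, 92 gave the same call, 136 were weaker and 16 reversed in sign. Counts below are of genes by limma unless lists are named, and each culture's count is against its own galactose arrays.

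Values as deposited gave 5 genes in early no3AT2 (25 centred) and 28 at steady state (66), 3 for the early difference between cultures without 3AT (5) and 1 for 3AT40mM minus no3AT in galactose (0). Quantile normalization gave 216 genes in early glucose over 3 chemostats (340), 21 up and 195 down, 19 in early no3AT (0), 61 at steady state in 3AT40mM (0), 0 in early no3AT2, 123 at steady state in no3AT2, 3 for the early difference and 14 in galactose. It moved HIS7 in early glucose to -0.0217 and the steady-state correlation between cultures without 3AT to 0.55 (0.65). At glucose steady state over 3 chemostats it gave 1225 genes (840), and 40.7% of them were up against 25.8%.

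Genes on all 22 arrays alone gave 6 in early no3AT, 11 at steady state in no3AT (4), 39 in early no3AT2, 3 for the early difference, 1 in galactose, and a median of 623 genes over 2-fold per array (1142). No 80% filter gave 42 at steady state in no3AT2. Robust and trended moderation gave 14 and 15 in no3AT2, early and steady.

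Leaving out no3AT gave 130 genes in early glucose and 366 at glucose steady state (840), HIS7 at -0.0281 in early glucose and HIS5 at 0.24 between glucose phases. Leaving out 3AT40mM gave 3 and 173 genes, HIS7 at -0.21, GAL1 at -0.0460 between glucose phases (0.52), and 7 list calls over the 3 comparisons (11). Leaving out no3AT2 gave 305 genes between glucose phases (0), 26 list calls and HIS5 at 0.31 in early glucose (-0.23). Without a chemostat block 0 and 432 genes passed.

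All 22 arrays in the fit gave 5 and 17 genes in no3AT, 58 and 100 in no3AT2, 24 for the early difference and 3 in galactose. Steady-state arrays only gave 355, 429 and 446 at steady state in no3AT, 3AT40mM and no3AT2, 3 for the steady-state difference between cultures without 3AT (0) and 11 in galactose. Early glucose as the first array only gave 0 genes over 3 chemostats, 8 in no3AT, 1320 in no3AT2 and 205 for the early difference, with HIS7 at -0.11. Early glucose as all arrays before steady state gave 616, 1 in no3AT, 1 for the early difference, HIS7 at -0.16 and an early correlation of 0.45 (0.25). With an estimated correlation 0 lists passed.

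Neighbour-corrected values gave 0 and 20 genes over 3 chemostats, 195 and 16 in no3AT2, correlations of 0.13 and 0.51 between cultures without 3AT, and a median of 690 genes over 2-fold. HIS5 turned to 1.06 early and 0.89 at steady state (-0.67), HIS4 to 0.43 (-0.25) and HIS7 to 0.46 (-0.41). With the chromosome arm median removed, 0 and 79 genes passed, 7 in early no3AT, 107 and 20 in no3AT2 and 1 in galactose, with HIS5 at 0.50 and 0.19, HIS4 at 0.56 and HIS7 at 0.20. With neighbour-corrected values and arrays as units 84 and 336 passed, with HIS5 at 1.06 and 0.89, HIS4 at 0.43 and HIS7 at 0.46. With neighbour-corrected values and without 3AT40mM at 552 hours, 0 and 0 passed over 3 chemostats, 82, 1267 and 577 early in no3AT, 3AT40mM and no3AT2, 115 for the early difference and 551 for 3AT40mM minus the others, with HIS5 at 1.38 and 0.89, HIS4 at 0.43 and HIS7 at 0.46.

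Leaving out 1 array gave between 0 and 522 genes in early glucose over 3 chemostats, between 302 and 1115 at steady state, and between 0 and 69 for the early difference between cultures without 3AT. In no3AT early, 136 without 344 hours of that culture and 54 without 3AT40mM at 552 or 574 hours. In no3AT at steady state, 0 without no3AT at 316 hours, 68 and 12 without its arrays at 507 and 526, 205 without 3AT40mM at 552 or 574, and 2 without either 3AT40mM galactose array, either early no3AT2 array or no3AT2 steady arrays 2 or 3. In 3AT40mM, 1332 early without 552 hours, and 65 at steady state without 552 or 574.

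In no3AT2 early, 5 without either no3AT galactose array or steady arrays 1 or 3, 9 without steady array 2, 4 without either 3AT40mM galactose array, 510 without 3AT40mM at 552 or 574 hours, 0 without no3AT2 at 315 and 102 without 328. In no3AT2 at steady state, 19 without either no3AT galactose array, 16 without no3AT at 344 or 353, 119 without 507 or 526, 4 without either 3AT40mM galactose array, 341 without 552 or 574, 22 without 315 or 328 and 0 without steady arrays 1 or 3.

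The steady-state difference between cultures without 3AT was 1 without no3AT at 344 or 353 hours and 2 without 507. The 3AT40mM early difference was 131 without 552 hours. In galactose, 3 passed without 3AT40mM at 552 or 574 hours, and 1 without no3AT at 507 or 526 or no3AT2 at 315 or 328. The early correlation lay between 0.11 and 0.35, at 0.11 and 0.14 without no3AT at 316 and 344 hours, and the steady one between 0.48, without 507, and 0.68. List calls were 18 without the no3AT2 galactose array and 7 without no3AT2 at 328 hours. HIS4 at steady state lay between -0.34 and 0.0843, the last without the no3AT2 galactose array. HIS7 in early glucose (0.00) lay between -0.18 and 0.18, and below 0 without no3AT at 316 and 344 hours, 3AT40mM at 522 and 574 and no3AT2 at 328. GAL1 between glucose phases lay between -0.11 and 1.08, and below 0 without no3AT at 526 hours and 3AT40mM at 574 and 937.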

Other observations

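Genes of gluconeogenesis and C2 use include 2 that fell in early glucose over 3 chemostats: SFC1, a mitochondrial carrier, at -1.34 (SE 0.30, adjusted p = 0.0183, lower in all 3) and ICL1, isocitrate lyase, at -1.29 (SE 0.36, adjusted p = 0.0449, lower in all 3). PCK1, which makes phosphoenolpyruvate, stood at -0.71 and MLS1, malate synthase, at -0.63, without passing. Without the array at 552 hours, 8 of 18 ergosterol synthesis genes and 5 of 12 purine synthesis genes rose in early 3AT40mM and 0 fell (medians 1.24 and 1.11), with 9 and 5 up when adjusted over the list alone, and 0 and 1 down.

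All tests below were chosen after the result was seen. Genes lower in glucose lie next to each other in the deposited order. In 22 of 22 arrays the correlation of values 48 rows apart was above that of values 47 rows apart, which position on the array may give and which gene order along chromosomes would not. Against gain or loss of the whole of chromosome X, its left arm was below its right arm in all 3 chemostats, by -1.25 on average (SD 0.23). For chromosomes I, III, IV and IX, which hold 340 of the 623 genes that fell at glucose steady state, it stays open: both arms had medians between -0.95 and -0.21, and in 0 of the 4 did the arms differ by over 0.2 in the same direction in all 3 chemostats. A change of these genes with the carbon source cannot be told apart from position: 15 of 840 genes passed also with the neighbour-corrected values. The sign was kept in 794, but the genes were called on the same arrays before the correction. Large changes mostly keep their sign when a smaller neighbour level is removed, so the kept signs decide nothing.

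The 3AT40mM array at 552 hours resembles galactose arrays. It differed over 2-fold in 1 gene from the galactose array at 522 hours, as a galactose culture under a glucose label would. From the galactose array at 477 hours it differed in 76 genes, more than the 23 between the galactose arrays. Its highest correlation with another array was 0.87, as a sample from before the cells had responded would also have, so that either may hold. Against a swap with a galactose array of the same chemostat, the galactose arrays at 477 and 522 hours differed from each other by 23 genes, while other glucose arrays of the culture differed from galactose by 461 or more.

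Amino acid biosynthesis genes under Gcn4 were lower in early no3AT2 than in its galactose array, as medians over the list. The change from galactose in no3AT2 minus that in no3AT had a median of -1.74 early and 0.46 at steady state. These are -2.20 apart, with 34 and 7 of 37 genes below 0. A shift from polyA RNA in place of total RNA that is equal in all phases would cancel in both, and so give neither. An effect of RNA type that differs between phases was not tested. The hours of sampling cannot be told apart from the culture: the lowest labelled hour in glucose of no3AT2 is 315, and the hours of the switches are not given.

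For the counts over 3 chemostats, 10 splits of the 6 means are too few for a share under 0.05. For early glucose against galactose 1 of the 10 splits gave as many genes as the real 340 (highest other 0). For glucose steady state against galactose it was 1 of 10 (840, highest other 0). For glucose steady state against early glucose the real count was 0 (highest other 67), which every split reaches, so that their number decides nothing there. Each chemostat gives 1 mean per phase, and 4 of the 10 splits part the phases of all 3 chemostats, as the block needs, while the other 6 part those of 1. Among these 4 the highest other counts were 0, 0 and 67. The split with 67 genes exchanges the phases of no3AT2, and what gives these 67 calls was not tested.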
